A study of Mus musculus with 18 samples.

How the data were processed

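RNA was measured in 18 spontaneous mammary gland tumors of mice, each from a different animal per the series design. Every genotype label carried the MMTV-Cre transgene, which drives Cre recombinase in mammary epithelium, and 1 allele of Pik3ca with the activating H1047R change, spelled "Pikca" in the labels. The tumors were grouped by the Cbfb part of the genotype label: 14 Cbfb(het), 3 Cbfb(wt) and 1 Cbfb(homo). The labels do not say which part of Cbfb was altered, and they name no batch, litter, age or sex. Per the labels' protocols, RNA was taken from freshly isolated tumors with Trizol, and libraries were made with the TruSeq stranded mRNA kit.

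The authors deposited 1 gene table per tumor with RSEM's expected counts and TPM. An expected count, per the file headers, is RSEM's estimate of the reads of a gene, with reads that fit several genes shared out between them, so it need not be whole, and it is not normalized. The deposited TPM values are scaled by gene length and to 1 total per tumor, so they carry no depth. The submitters' processing notes name STAR 2.7.0f, RSEM 1.3.1 and the mm10 build. The order of the steps, the strand setting and the annotation release are not given in the sources used here. All 55450 gene IDs in the files, version included, occur in GENCODE release M21 of GRCm38, and positions given here come from it. The deposited FPKM column was not used. Between 6.20% and 7.19% of the expected counts of a tumor were not whole, and all were rounded to whole numbers before any count model. The total per tumor was 33210246 to 40974153 rounded expected counts.

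The main comparison set the 14 Cbfb(het) against the 3 Cbfb(wt) tumors with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr, libraries were scaled with TMM factors, and the quasi-likelihood F-test was used with robust dispersion estimates and no covariate. This left 18475 genes. P-values were adjusted over genes by the Benjamini-Hochberg method, with a threshold of 0.05 and no fold threshold. The standard error of a log2 fold change was taken as its size divided by the square root of F. Levels per tumor are log2 CPM with TMM factors and a prior count of 2. Cbfb itself was compared with a two-sided exact permutation test over all 680 splits of the 17 tumors into 14 and 3. The Cbfb(homo) tumor has no replicate and entered no test.

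Before the data were examined, 51 gene lists for pathways and cell types, the named genes, the comparisons and most alternatives were fixed. A list was tested if at least 5 members passed the filter, which held for 50 lists. Lists were tested with camera of limma 3.58.1 on voom values, with the inter-gene correlation preset to 0.01, and again with the correlation estimated for each list. The fry test was run beside it. List p-values were adjusted over the 50 lists. The log2 fold change given for a list is the median of its members. Its level in a tumor is the mean log2 CPM of its members. In the Cbfb(het) tumors, Cbfb was correlated with a score of each list by a two-sided permutation test with 100000 resamples. This score is the mean over members of their log2 CPM standardized over the tumors correlated. For the Cbfb(homo) tumor, the median log2 ratio of a list was placed among 10000 random lists of the same size matched on mean expression.

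The rule for named genes always took Cbfb, Pik3ca, Runx1, Runx2, Runx3, Notch3, Tufm and Hnrnpk. It took up to 12 genes past the threshold in each direction, and where fewer than 5 passed, the 5 genes of that direction with the smallest p and a mean log2 CPM of at least 1, given as values. It added the member with the smallest p from each of 4 mitochondrial lists, the autophagy list and the Notch list. For the Cbfb(homo) tumor it took the 5 genes farthest above and the 5 farthest below the range of the other 17 tumors, where genes above needed a log2 CPM of at least 3 in that tumor and genes below a mean of at least 3 over the others. Unnamed gene models and immunoglobulin or T cell receptor segments were passed over. Other genes named as members of a list, the genes that describe single tumors, and Tex11 were chosen after their values were seen.

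The gene and list tests were tested on simulated counts with the means, library sizes and group sizes of the 17 tumors, in 3 simulations over 18475 genes. The changed genes were drawn from those with a mean log2 CPM of at least 1, so the rates do not cover genes of lower level. The test called 11.3% of genes changed 2-fold, 71.3% of those changed 4-fold, 88% of those changed 8-fold and 91.3% of those changed 16-fold. It called 18 of 54645 unchanged genes. Each of the 4 folds was given to 150 genes over the 3 simulations. Where so many genes change, the adjusted threshold is easier to reach, so the rates overstate the power for a few changed genes. A simulated list of 60 genes raised by 0.5 on the log2 scale had a camera p of 2.03e-11 or less in all 3 simulations. The simulated genes varied independently of each other, which the genes of a pathway in tumors do not.

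Alternatives were RLE and upper-quartile scaling, DESeq2 1.42.0, limma-voom without and with sample quality weights, no filter on low counts, a filter of 1 CPM in at least 3 tumors, a fit of all 18 tumors with Cbfb(homo) as its own group, the mean standardized level of the epithelial list as a covariate, and leaving out each of the 17 tumors in turn. Averaging Cbfb(het) tumors 10 and 14 as 1 sample, and correlating only within the main run of Cbfb levels, were added after the data were seen. Pairs of tumors were compared by a chi-square test of their counts over genes with at least 20 counts in the pair, and genes of low count were those with at most 200. For each chromosome, the median over its genes of the log2 deviation from the gene's median over 18 tumors was taken, for genes with a mean log2 CPM above 3. Figures were drawn with matplotlib 3.10.9.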

Results

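The series profiled RNA from 18 mammary tumors of mice that carried a Cre-activated oncogenic Pik3ca allele together with a Cbfb allele labelled het (14 tumors), wt (3 tumors) or homo (1 tumor). Cbfb encodes the subunit that stabilizes DNA binding of the RUNX transcription factors. Per the series design, each tumor came from its own mouse. Depth was even, from 33210246 to 40974153 rounded expected counts per tumor, but its use was not: milk protein genes took from 0.0297% to 15.2% of a tumor's counts. The design compares Cbfb genotypes in Pik3ca-mutant tumors, and the mitochondrial lists were chosen before the values were seen.

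Cbfb RNA was not lower in the tumors labelled Cbfb(het) than in those labelled Cbfb(wt). Cbfb (ENSMUSG00000031885.14) is a protein-coding gene on the plus strand of chromosome 8, from 105170674 to 105217989 in GRCm38. Its level was 5.74 ± 0.63 log2 CPM in Cbfb(het) tumors (SD, n = 14) and 5.13 ± 0.82 in Cbfb(wt) tumors (SD, n = 3). The difference of 0.61 lay within the spread between tumors (two-sided exact permutation test, p = 0.156, where the smallest possible p is 0.00147). The Cbfb(homo) tumor had the lowest level of the 18, 4.19, with 773 counts and 10.8 TPM. The library labelled Cbfb(wt) 2 was almost as low, at 4.26 and 12.03 TPM, while the libraries labelled Cbfb(wt) 1 and 3 stood at 5.87 and 5.26. Among Cbfb(het) tumors, 11 lay between 5.40 and 5.85, tumor 1 lay at 4.49, and tumors 10 and 14 lay at 6.997 and 6.971 (71.1 and 70.6 TPM). Without the library labelled Cbfb(wt) 2 the fitted difference was 0.28, and without Cbfb(wt) 1 it was 1.03. Gene-level counts cannot show a transcript that lacks an exon, and the directions below are those of the labels.

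**Figure D1:**
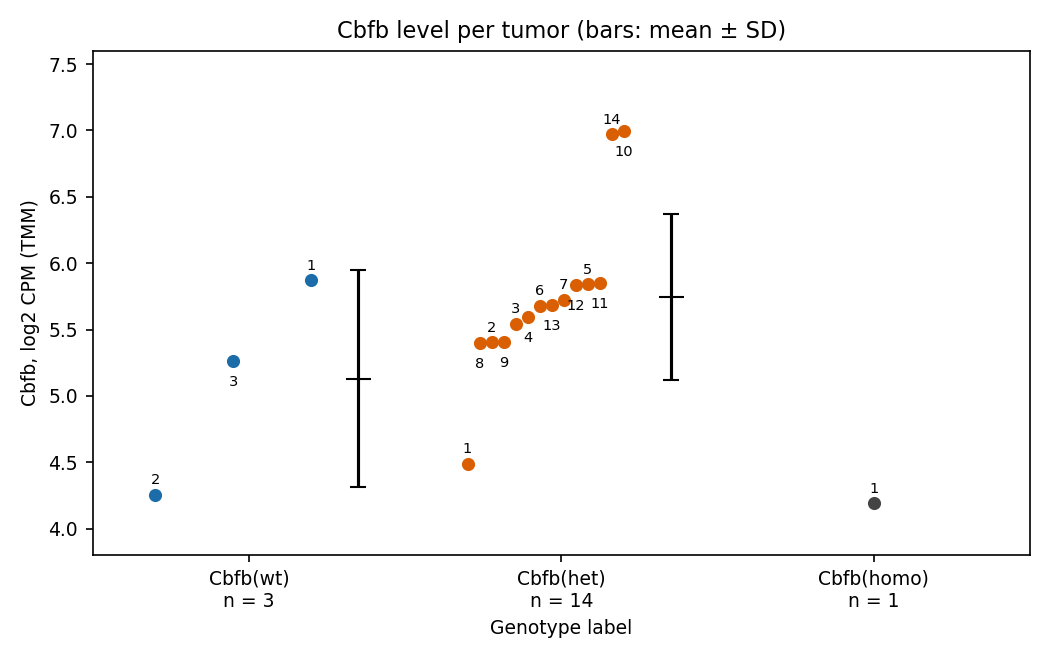
Cbfb level (log2 CPM with TMM factors, y axis) in each tumor by genotype label (x axis), with replicate numbers at the points and black bars for mean ± SD of the 14 Cbfb(het) and 3 Cbfb(wt) tumors. Cbfb(wt) 2 at 4.26 and the Cbfb(homo) tumor at 4.19 lie lowest, and Cbfb(het) 10 and 14 at 6.997 and 6.971 lie highest.

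No single gene passed the adjusted threshold between the tumors labelled Cbfb(het) and those labelled Cbfb(wt). Among the genes with the smallest p on the higher side were H2afy2, a macroH2A histone variant gene, with a log2 fold change of 1.66 ± 0.49 (SE), and Hoxb2, a homeobox gene, with 2.35 ± 0.71. Gpx3, the secreted glutathione peroxidase, stood at 1.45 ± 0.46, Aoc3, a vascular amine oxidase, at 1.52 ± 0.49 and Pex19, a peroxisome assembly factor, at 0.38 ± 0.11. Pex19 was higher in all 14 Cbfb(het) tumors than in any Cbfb(wt) tumor. On the lower side were the mismatch repair gene Msh6 at -0.74 ± 0.16, Intu, a planar polarity and cilium gene, at -0.88 ± 0.24, and Dkc1, the dyskerin gene of snoRNPs and telomerase, at -0.65 ± 0.18. Stc1, a secreted glycoprotein hormone gene, stood at -3.49 ± 0.83 and Agps, an ether lipid synthesis gene, at -1.60 ± 0.45. Each of these last values came from 1 tumor. Stc1 was at 9.55 log2 CPM in Cbfb(wt) 2, and its log2 fold change was 0.76 without that tumor. Agps was at 10.04 in Cbfb(wt) 3, and its log2 fold change was 0.39 without it. All 10 genes had an adjusted p of 0.999 (edgeR quasi-likelihood test, Benjamini-Hochberg).

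The genes of the RUNX complex and its signaling context likewise showed no difference past the threshold, each with an edgeR adjusted p of 0.999. Pik3ca had a log2 fold change of -0.36 ± 0.20 (SE), Runx1 of -0.12 ± 0.25, Runx2 of -0.57 ± 0.65 and Runx3 of -0.09 ± 0.58. Without Cbfb(wt) 2, Runx2 turned to 0.88 and Runx3 to 0.85. That tumor held the highest level of both, 6.55 and 6.15 log2 CPM. Notch3, a Notch receptor gene, was at -0.12 ± 0.55 in the fit, while its mean log2 CPM was 6.35 in Cbfb(het) and 6.13 in Cbfb(wt) tumors. Hnrnpk, which encodes an RNA-binding protein, was at 0.02 ± 0.13.

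Of 18475 genes tested, edgeR called 0 higher and 0 lower in Cbfb(het) tumors. At an unadjusted p under 0.05 there were 623 genes, 270 higher and 353 lower. Evenly spread p-values would give 924. Of 100 splits of the same tumors into 14 and 3, 46 gave at least 623 such genes. The splits other than the labels had a median of 571. The labels thus gave a number usual for a random split. DESeq2, limma-voom and limma-voom with sample quality weights also called 0 genes, with 932, 489 and 970 at an unadjusted p under 0.05. With 14 against 3 tumors, the common biological coefficient of variation was 0.691. Among simulated genes with a mean log2 CPM of at least 1, most 4-fold changes but 11.3% of 2-fold changes were called. Most 2-fold changes would thus be missed. The rates hold where many genes change at once, and a lone changed gene would need a smaller p. The fit without a low-count filter, and the fit of all 18 tumors, each called 1 gene lower, Tex11, a germ cell gene on the X chromosome (adjusted p = 0.0259 and 0.0175). Tex11 had 3049 counts (39.1 TPM) in Cbfb(wt) 2 and at most 3 counts in every other tumor.

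Mitochondrial gene groups differed little between the genotypes. Of 75 nuclear genes of the respiratory chain, 71 had a positive fold change and the median was 0.21 on the log2 scale, with Atp5e, an ATP synthase subunit gene, at 0.70 ± 0.31 (SE). The 82 genes of the mitochondrial ribosome had a median of 0.08, with 61 positive and 21 negative, and Mrpl17 stood at 0.45 ± 0.23. The 44 factors of mitochondrial transcription and translation were divided into 21 positive and 23 negative around a median of -0.04. Among them Tufm, the mitochondrial elongation factor Tu gene, stood at 0.10 ± 0.27 and Gfm1, an elongation factor G gene, at -0.34 ± 0.19. The 13 genes encoded by mitochondrial DNA had a median of 0.05, with mt-Atp6 at 0.77 ± 0.34. No member of these lists passed the edgeR threshold of adjusted p over all genes, and none passed when adjusted over the list alone.

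By camera with the preset correlation, the nuclear respiratory chain list had an adjusted p of 4.15e-05 and the mitochondrial ribosome list of 0.0427. Both calls were lost with an estimated correlation (adjusted p = 0.837). The translation factors had an adjusted p of 0.526 and the mitochondrial DNA list of 0.704. With the epithelial score as a covariate the respiratory chain median was 0.09 (adjusted p = 0.264) and the ribosome median 0.05 (adjusted p = 0.743), and the translation factors were at -0.14 (adjusted p = 0.00348). Leaving out any 1 of Cbfb(het) tumors 1, 2, 3, 5, 7, 8 and 9, or any 1 Cbfb(wt) tumor, also ended the mitochondrial ribosome call, with medians from 0.03 to 0.13. Without Cbfb(wt) 2 the translation factors were at -0.15 (adjusted p = 0.0176), and without Cbfb(wt) 3 at 0.12.

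**Figure D2:**
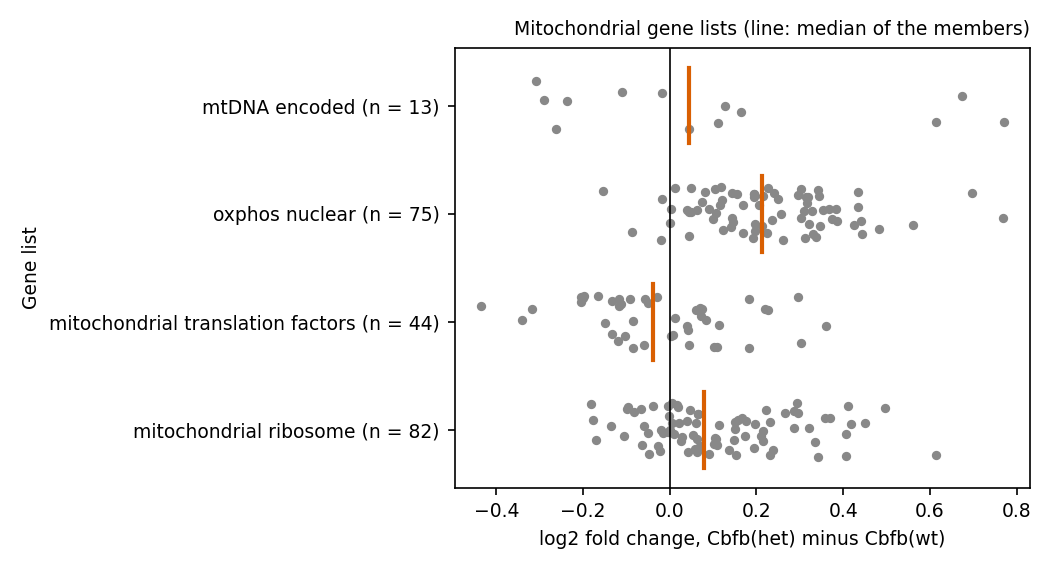
Log2 fold changes, Cbfb(het) minus Cbfb(wt), of each member (points, spread vertically for legibility) of 4 mitochondrial gene lists (y axis, with the number of members). Orange lines mark the medians, 0.08, -0.04, 0.21 and 0.05 from bottom to top, and no point passed the test of single genes.

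Gene groups of fat, antibody-producing cells and blood stood higher in the tumors labelled Cbfb(het), and proliferation genes lower, by camera with the preset correlation. None of these list calls held with an estimated correlation (smallest adjusted p = 0.837). All 17 adipocyte genes had a positive log2 fold change, with a median of 2.57. Among them Adipoq, the adiponectin gene, stood at 5.16 ± 2.28 (SE) and Fabp4, a fatty acid carrier gene of adipocytes, at 2.57 ± 1.13. Of 16 B and plasma cell genes 14 were positive, with a median of 3.10, and the antibody genes Igkc and Jchain stood at 4.32 ± 1.72 and 3.98 ± 1.66. The B and plasma cell list as a whole was low, with a mean level of -0.13 log2 CPM in Cbfb(het) and -1.64 in Cbfb(wt) tumors. All 7 erythroid genes were positive (median 1.74), as were all 20 basal and myoepithelial genes (median 0.91), where Krt5 stood at 0.87 ± 0.98 and Acta2 at 1.01 ± 0.85. The 74 cytosolic ribosomal protein genes had a median of 0.29, with 71 positive, and Rpl41 stood at 0.50 ± 0.28. Cell cycle genes had a median of -0.22, with 32 of 40 negative. Mki67 stood at -0.51 ± 0.26 and Top2a at -0.60 ± 0.34. Immediate early genes also had a median of -0.22, with 18 of 22 negative, among them the growth factor response genes Fos at -0.70 ± 0.28 and Egr1 at -0.88 ± 0.34. No member of any list passed the edgeR threshold, over all genes or adjusted over the list alone.

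In all, camera with the preset correlation put 16 lists higher and 2 lower, out of 50 tested. The higher lists also held cholesterol synthesis (median 0.35), epithelial (0.19), interferon response (0.41), fibroblast (0.82), milk (0.74), Wnt target (0.34), hair follicle (2.05), estrogen response (0.43) and alveolar progenitor genes (0.38). With an estimated correlation 0 lists passed (smallest adjusted p = 0.837), and with fry 0 passed (smallest adjusted p = 0.880). The exact permutation test of list levels (mean log2 CPM) gave 0 lists, with a smallest adjusted p of 0.735 over the 50 lists and 3 lists under an unadjusted p of 0.05. Its smallest possible p, with 680 splits, is 0.00147. A single list could thus not pass after adjustment over 50 lists, so this 0 says little. Leaving out the library labelled Cbfb(wt) 2 ended 11 of the 18 preset calls: the epithelial list passed as lower (median -0.38, adjusted p = 0.00159), and those that no longer passed included cell cycle (median -0.073, adjusted p = 0.0945), interferon response (0.12, adjusted p = 0.802), milk (0.16, adjusted p = 0.760), basal (0.67, adjusted p = 0.126), hair follicle (1.496, adjusted p = 0.653) and alveolar progenitor genes, whose median turned to -0.19 (adjusted p = 0.150). Without Cbfb(wt) 1 the median of immediate early genes turned to 0.20 (adjusted p = 0.527) and that of Wnt targets to -0.078 (adjusted p = 0.742). Without Cbfb(wt) 3 the fibroblast median was 0.25 (adjusted p = 0.837) and the cholesterol synthesis median 0.22 (adjusted p = 0.181). The erythroid median was 1.39 without Cbfb(wt) 1 (adjusted p = 0.0737) and 1.29 without Cbfb(wt) 3 (adjusted p = 0.233). The estrogen response median ran from 0.20 without Cbfb(het) 4 (adjusted p = 0.0726) to 0.90 without Cbfb(wt) 3 (adjusted p = 0.235). Every 1-tumor omission left 4 lists called in the same direction: cytosolic ribosome, adipocyte, B and plasma cell and nuclear respiratory chain genes. Other settings ended further calls. With quality weights the interferon response median turned to -0.13 (adjusted p = 0.225) and the basal median was 0.15 (adjusted p = 0.109). With the epithelial covariate the Wnt target median was 0.057 (adjusted p = 0.127), and with DESeq2 the epithelial list (adjusted p = 0.575) and the milk list (adjusted p = 0.268) did not pass. Of the 18 calls, 3 held in every alternative that kept camera with the preset correlation: cytosolic ribosome, adipocyte and B and plasma cell genes. The alveolar progenitor call held in 10 of 27 such alternatives and ended without any 1 of 9 Cbfb(het) tumors. The other 32 lists had adjusted p-values from 0.0579 to 0.972. In squamous and mesenchymal transition genes the median and camera differed in sign, and in RUNX target genes the median was -0.11 and the mean 0.86.

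Within the 14 Cbfb(het) tumors, the Cbfb level was set against the 50 list scores. The levels fell into separate runs of 1, 11 and 2 tumors, so no coefficient over all 14 is given. In the run of 11 tumors, 0 of 50 lists passed the adjusted threshold (permutation test, smallest adjusted p = 0.166 for Pearson's r and 0.186 for Spearman's rho). Mitochondrial ribosome, respiratory chain and translation factor genes were among the lists that did not pass. Their Pearson's r in this run was -0.66, -0.68 and -0.53 (permutation test, adjusted p = 0.245, 0.219 and 0.325). Coefficients of this size were not particular to mitochondrial lists. In the same run r was -0.81 for replication histone genes, -0.69 for milk genes, -0.67 for glycolysis genes and 0.71 for RUNX partner genes. With 11 tumors the lack of a passing list does not exclude a relation. Over all 14 tumors, 0 lists passed on log2 CPM (smallest adjusted p = 0.0752 for Pearson's r and 0.0510 for Spearman's rho). On log2(TPM + 1), which has no TMM scaling, 2 lists passed by Pearson's r and 5 by Spearman's rho, across separate runs of Cbfb. The latter included mitochondrial DNA genes (permutation test, adjusted p = 0.0385) and autophagy genes (adjusted p = 0.0268). On log2 CPM these 2 lists had adjusted p-values of 0.618 and 0.953 by the same test. In the run of 11 tumors their rho was negative, -0.39 and -0.41 (adjusted p = 0.407 and 0.382). The highest run held only tumors 10 and 14, whose libraries were nearly alike.

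The single tumor labelled Cbfb(homo) was set against the other 17 as a description, without a replicate and without a test. Its cell cycle genes had the lowest mean level of the 18 tumors, 4.21 log2 CPM against 4.58 to 5.82 elsewhere. Its mitochondrial chaperone and protease genes were also lowest, 5.93 against 6.03 to 6.50. Basal and myoepithelial genes were highest in it, 8.21 against 4.74 to 7.28, with the basal keratin gene Krt14 at 13.34. Pericyte and smooth muscle genes (5.57 against at most 4.78), endothelial genes (5.10 against 4.81), hormone-sensing luminal genes (6.002 against 5.90), p53 target genes (5.68 against 5.38) and Notch pathway genes (4.72 against 4.64) were likewise highest in this tumor. Esr1, the estrogen receptor gene, was at 4.79 log2 CPM in it and at 5.29 in Cbfb(het) 4. Markers of other cell types thus moved together with the label in this tumor.

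The mitochondrial ribosome list of the Cbfb(homo) tumor lay 0.26 below the mean of the Cbfb(wt) tumors on the log2 scale (median -0.26), at percentile 0.03 of random lists. The translation factors were at -0.25 (percentile 0.36), while the respiratory chain list was at -0.07 (percentile 43.8) and the mitochondrial DNA list at -0.10 (percentile 24.6). Against the mean of the 14 Cbfb(het) tumors, the ribosome list was at -0.34 (percentile 0) and the translation factors at -0.28 (percentile 0.03). The respiratory chain was at -0.27 (percentile 0) and the mitochondrial DNA list at -0.05 (percentile 48.3), so the place of the respiratory chain depended on the reference. Random lists hold unrelated genes, while members of a list varied together (estimated correlation 0.51 in the ribosome list). Extreme percentiles were common: against Cbfb(wt), cell cycle genes were at 0 and fibroblast and endothelial genes at 100. The percentiles thus do not show that the mitochondrial lists stood out. The level of the mitochondrial ribosome list, 4.45, ranked 16 of 18, and Cbfb(het) tumors 11 and 12 were lower at 4.41 and 4.44. The translation factors ranked 15 of 18, the respiratory chain 12 and the mitochondrial DNA list 10. Single genes far above the other tumors were Kcne2, a potassium channel subunit gene, at 4.29 log2 CPM against at most -2.37, and Olfm4, a secreted glycoprotein gene of epithelial crypts, at 6.49 against at most 2.80. Slc38a5, an amino acid transporter gene, was at 3.96, Rasgrf1, a Ras exchange factor gene, at 5.61 and Cyp3a57, a cytochrome P450 gene of a family with close copies, at 3.86. Far below were Hs3st3b1, a heparan sulfate sulfotransferase gene, at 1.01 against at least 2.61, Galm, the galactose mutarotase gene, at 1.79 and Ermp1, an endoplasmic reticulum protease gene, at 5.72. Eno1b (4.98 against at least 7.55) and the pseudogene Rbpj-ps3 (-0.93) share sequence with Eno1 and Rbpj, and their values are uncertain. In this tumor 492 genes lay above and 474 below all others, within the 49 to 1676 and 87 to 1261 seen in other tumors.

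Tumors differed widely within the labels. The first principal component of the 17 Cbfb(het) and Cbfb(wt) tumors held 41.2% of the variance, and the genotype label explained a median of 2.60% of the variance per gene, while other random splits of the tumors gave a median of 3.07%. Epcam, an epithelial adhesion gene, was at 2.45 log2 CPM in Cbfb(wt) 2, and at 4.84, 4.88, 6.31 and 6.79 in Cbfb(het) tumors 10, 14, 1 and 12, while the other 13 tumors lay between 8.38 and 9.51. Vim, an intermediate filament gene of mesenchymal cells, was at 11.24 to 11.95 in those 5 tumors and at 7.28 to 9.62 in the rest. The bone and cartilage matrix genes Ibsp and Acan were at 7.19 and 8.74 in Cbfb(het) 10 and at 7.09 and 8.79 in Cbfb(het) 14. Csn2, the beta-casein gene, reached 16.05 in Cbfb(het) 8 and was near the floor, at -4.25, in Cbfb(wt) 2 and Cbfb(het) 10.

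**Figure D3:**
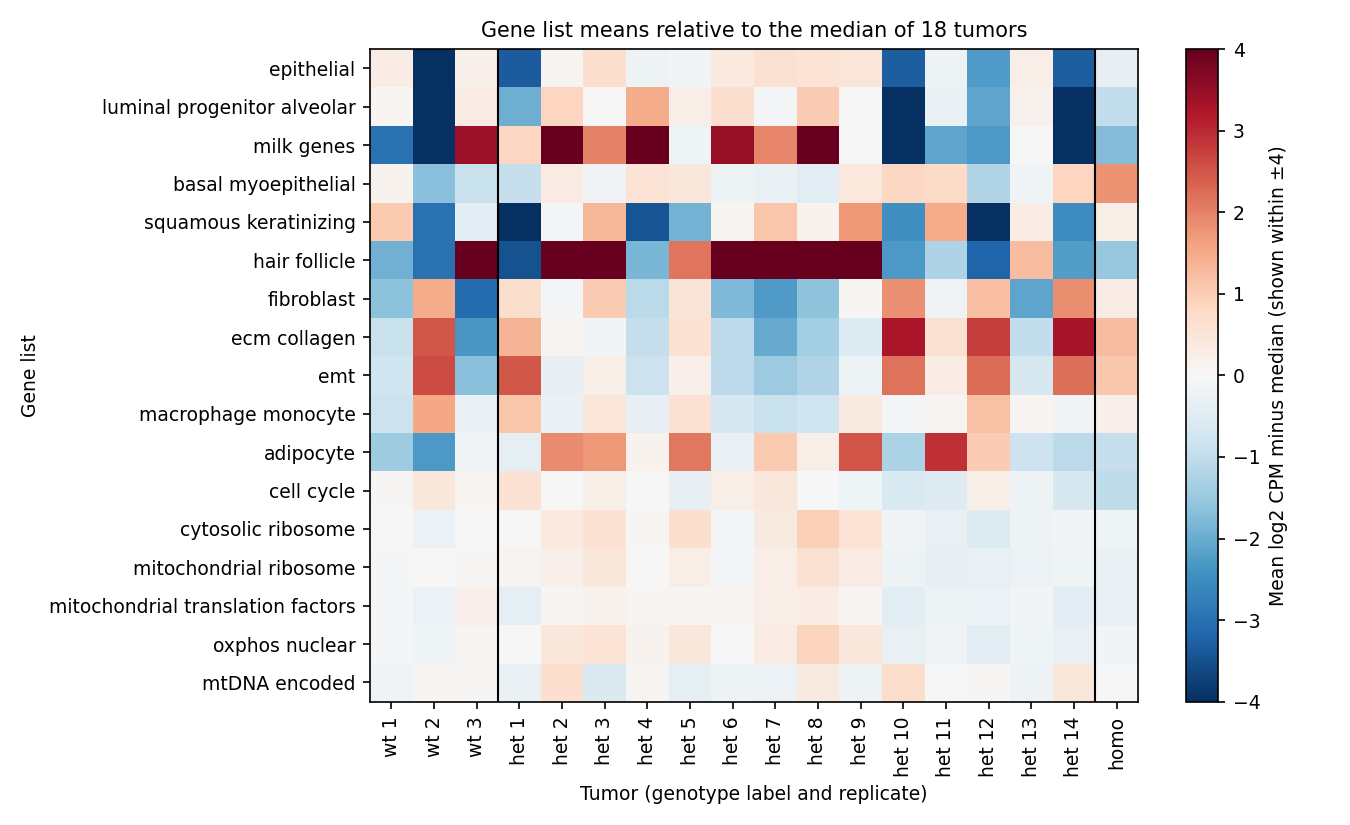
Mean log2 CPM of 17 gene lists (y axis) in each tumor (x axis, by genotype label and replicate) minus the median of that list over 18 tumors, with colors limited to 4 on either side. Epithelial genes are lowest in Cbfb(wt) 2 and in Cbfb(het) 1, 10, 12 and 14, hair follicle genes run from -3.65 to 7.83 log2 CPM and milk genes from -1.16 to 10.83.

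The libraries of Cbfb(het) tumors 10 and 14 were nearly alike. Their counts differed by a chi-square of 4.18 per degree of freedom over 16196 genes, against at least 85.9 in the other pairs of the 153. Of the 12357 genes above low count, 11 differed more than 2-fold. The difference exceeded counting error over all genes, while the chi-square was 1.48 among genes of low count, and no known repeat run gave a value to compare. Both were kept in n = 14 as the design was fixed, and p-values treat them as independent. Averaged as 1 sample, they left the gene counts at 0 and gave 19 higher lists, and the Cbfb difference was 0.52 (two-sided exact permutation test over 560 splits, p = 0.216). Expression shifted over whole chromosomes in both: chromosome 3 had a median of -0.55 and -0.56, chromosome 12 of -0.49 and -0.54, and chromosome 16 of 0.45 and 0.42 on the log2 scale. In Cbfb(wt) 2 the median of X chromosome genes was 0.57, and in Cbfb(het) 12 that of chromosome 7 was -0.46.

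**Figure D4:**
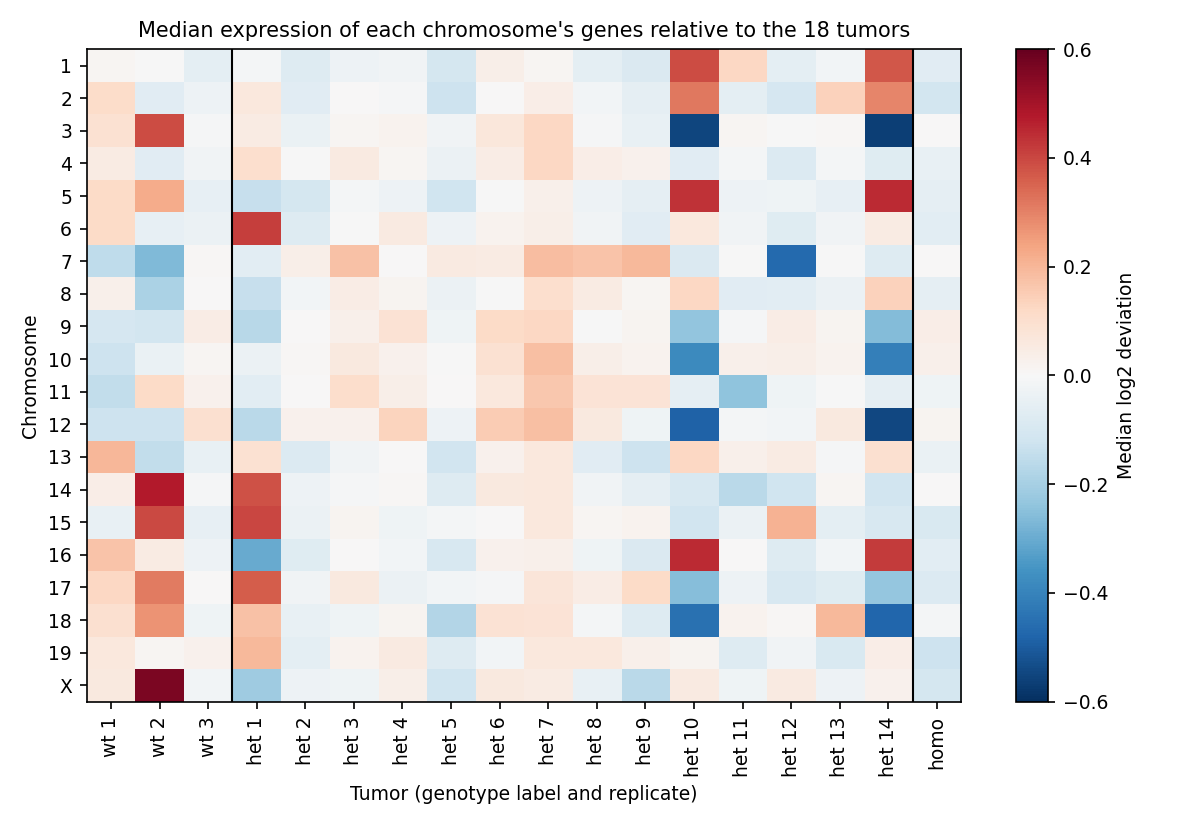
Median log2 deviation of the genes of each chromosome (y axis) in each tumor (x axis) from the gene's median over 18 tumors. Cbfb(het) 10 and 14 share their pattern, with chromosome 3 at -0.55 and -0.56, and Cbfb(wt) 2 has its highest value, 0.57, on the X chromosome.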

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

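Averaging Cbfb(het) tumors 10 and 14, and correlating within the main run of Cbfb levels, were chosen after the data were seen; the other alternatives were planned. The Cbfb difference kept its sign and stayed short of the threshold in all 27 alternatives, and 0 genes were called higher in each. Genes lower numbered 1 without a low-count filter and 1 in the fit of 18 tumors, carried by Cbfb(wt) 2. Lists higher fell from 16 to 10 without the filter, which adds genes to the background, and to 0 with an estimated correlation. Lists lower were 4 with DESeq2, 4 with the epithelial covariate, 0 with an estimated correlation, and 2 to 4 when 1 tumor was left out. The mitochondrial ribosome median passed no more at 0.10 without the filter, 0.081 in 18 tumors, 0.049 with the covariate, 0.080 with an estimated correlation, and 0.033 to 0.13 with 1 tumor left out. The respiratory chain missed at 0.091 with the covariate and 0.21 with an estimated correlation. Translation factors were at 0.034 with quality weights, -0.14 with the covariate and -0.15 to 0.12 with 1 tumor left out. Mitochondrial DNA genes were at -0.035 with limma-voom and -0.15 to 0.078 with 1 tumor left out. With quality weights Runx3 was at 0.15 and Hnrnpk at -0.037, with limma-voom Notch3 was at 0.23, and with the covariate Runx2 was at 0.19, Runx3 at 0.42 and Tufm at -0.10. With 1 tumor left out, Notch3 ran from -0.62 to 0.45, Runx2 from -0.97 to 0.88, Runx3 from -0.47 to 0.85, Hnrnpk from -0.029 to 0.11, Stc1 from -4.06 to 0.76 and Agps from -2.07 to 0.39. Correlated lists numbered 1 without the 2 tumors farthest in Cbfb (glycolysis) and 2 on log2(TPM + 1) by Pearson's r (Notch pathway and milk genes), or 5 by Spearman's rho, with mitochondrial DNA, autophagy and PI3K feedback genes added. Beyond the left-out tumors and the estimated correlation itself, the cause was not tested. Of the other values of named genes, 606 kept their direction and side of the threshold.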

Other observations

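Hair follicle genes, mostly hair keratins and trichohyalin, ran from -3.65 to 7.83 log2 CPM over the 18 tumors. Their mean level was 5.03 log2 CPM in Cbfb(wt) 3 and 5.94, 6.49, 5.72, 6.51, 5.09 and 7.83 in Cbfb(het) tumors 2, 3, 6, 7, 8 and 9. It was 1.98 in Cbfb(het) 5, 1.06 in Cbfb(het) 13, and -1.40 or less in each of the other 9 tumors. Wnt target genes such as Axin2 and Lef1 had their 7 highest mean levels, 3.34 to 4.34, in those first 7 tumors (the lists share Msx2), while Cbfb(het) 13 followed at 2.87. Milk genes did not sort the tumors the same way, since Cbfb(het) 4 had a milk level of 10.58 and a hair follicle level of -2.00. The labels give no group that matches this division, and no explanation was tested.

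Skeletal muscle genes stood at 7.47 in Cbfb(het) 5, 4.49 in Cbfb(het) 1, 3.89 in Cbfb(het) 11, 3.18 in the Cbfb(homo) tumor and 2.97 in Cbfb(het) 3, and at 0.61 or less in the other tumors. The salivary gland list had fewer than 5 members past the filter and was highest, at 0.82, in Cbfb(het) 4. Mast cell genes ran from -1.81 in Cbfb(het) 4 to 3.76 in Cbfb(het) 3.

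The tests of the likeness of Cbfb(het) 10 and 14 and of the Cbfb level were chosen after the result was seen. The splits of the tumors and the tests with the covariate and without Cbfb(wt) 2 were chosen before. For the 0 genes called between Cbfb(het) and Cbfb(wt), the count over splits carries no information, since all 100 of 100 splits must give at least 0 genes. Among the other splits, 15 gave at least 1 gene and 2 gave 100 or more, with a median of 0. The highest gave 2233 and placed 3 of the 5 tumors with the lowest Epcam in the small group. A split with 2 of those tumors, Cbfb(wt) 2 and Cbfb(het) 10 beside Cbfb(wt) 1, gave 0 genes. The highest split alone thus does not settle whether epithelial content carried its calls. For the 18 lists called with the preset correlation, 71 of 100 splits gave at least as many. The other splits had a median of 20 and a highest of 29. The labels thus called no more lists than a typical random split, and chance cannot be excluded. Genotype differences hidden by epithelial content or by a wrong label on Cbfb(wt) 2 stay open: 0 genes passed with the epithelial covariate and 0 without Cbfb(wt) 2, under the 20 set beforehand, but with the power of this design that bound was wrong, and genes at an unadjusted p under 0.05 went from 623 to 1079 and 580. Genotype effects of 2-fold, of which 11.3% were called in simulated counts, and part of those of 4-fold, of which 71.3% were called, may remain undetected. These rates are for genes with a mean log2 CPM of at least 1 in simulations where many genes changed at once. No changes were simulated in genes of lower level, and where few genes change the rates would be lower.

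Cbfb(het) tumors 10 and 14 were nearly identical although each tumor is said to come from its own mouse. Low Epcam shared by unrelated tumors is argued against as the sole reason. The other pairs among the 5 tumors with the lowest Epcam had a chi-square of at least 233 per degree of freedom. These pairs do not cover a type held by tumors 10 and 14 alone. Krt14 was at 12.58 and 12.64 log2 CPM in them, and at 6.95, 7.26 and 9.50 in Cbfb(het) 1, Cbfb(het) 12 and Cbfb(wt) 2. How alike unrelated tumors of such a type would be is not known here. A repeat run or preparation of 1 library stays open: the chi-square of 4.18 exceeds counting error alone, but it was 1.48 among genes of low count, and without a known repeat it cannot exclude small effects of a run or of ambiguous reads. A common origin in 1 tumor, as separate pieces, extractions or a graft, is another possible explanation, and the chromosome medians do not decide it, since their correlation of 0.998 follows from the likeness of the genes themselves. The labels cannot decide this, and genotypes from reads were not analysed here.

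Cbfb RNA did not follow the labels in Cbfb(wt) 2, which was low, and in Cbfb(het) 10 and 14, which were high. A copy gain of the whole region that alone explains the Cbfb level is argued against in tumors 10 and 14. The 73 expressed genes within 5 Mb of Cbfb had median deviations of 0.16 ± 0.17 (SE) and 0.24 ± 0.17, against 1.36 and 1.33 for Cbfb. A gain that explains part of the level stays open, given these errors. Within 1 Mb the medians were 0.33 ± 0.23 (SE) and 0.35 ± 0.23, the highest of the 18 tumors. As these libraries were nearly alike, their ranks do not count as separate observations. A focal gain is thus not shown, but it stays open. A copy loss of the 5 Mb on either side that alone explains the level is argued against in Cbfb(wt) 2. There the genes within 5 Mb had a median of -0.14 ± 0.23 (SE) against -1.38 for Cbfb. Over chromosome 8, which holds Cbfb, the lowest medians of the 18 tumors were -0.19 in Cbfb(wt) 2 and -0.14 in Cbfb(het) 1. The highest were 0.13 and 0.14 in Cbfb(het) 10 and 14, while the Cbfb(homo) tumor was at -0.05. A copy change that explains part of the Cbfb levels thus stays open. Low epithelial content, a wrong label on Cbfb(wt) 2 and regulation within the tumor stay open as possible explanations: 3 of the other 4 tumors with the lowest Epcam had Cbfb above the median of 18, but these include tumors 10 and 14, and Cbfb(het) 1 was low.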
